A study of Mus musculus with 8 samples.

How the data were processed

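The values analysed were spot intensities from a chemiluminescent antibody array for mouse cytokines, as deposited by the authors on a linear scale. Each of 8 membranes carried 111 analytes in duplicate spots, or 222 spots. The processed files of the individual membranes and the combined table of the series held identical values, with 0 differing. The image analysis software and the way background was removed are not given in the sources used here. Spots of 0.001 or 0.0011 stood in for spots without signal, 5 of them on the TC-1 membranes and 98 on the TC-1/IR membranes. A correction for background by the authors before deposit was inferred from these placeholders and is not stated in any source used here.

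The values held no reference spots and no negative-control spots, so no scaling to such spots was made and the intensities were used as deposited. The duplicate spots of an analyte were averaged. Values below a floor were set to it before taking log2. The floor had been fixed as 1% of the highest analyte, without saying whether per membrane or overall. After the values were seen it was read as 1 value for all membranes, 2.49, from the highest analyte of 249. Gene symbols came from the Entrez identifiers of the analytes, all 111 of which were found in a RefSeq gene table. No genome coordinates were used, since proteins were measured.

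The choices that follow were made before the data were examined. In a comparison of 2 single membranes an analyte was called higher or lower by a rule of size. The rule asked for at least 1.5-fold, at least 1 membrane above the floor and duplicate spots that did not overlap. Such comparisons have no p-value, and a fold against a value at the floor is given as "at least". That bound refers to the mean of the duplicate spots and does not cover their spread. Standard errors of these log2 ratios came from the duplicate spots and cover technical error only.

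Across the 8 membranes, limma was fitted to log2 values with additive terms for line, irradiation (RT) and rhIL-7-hyFc (IL-7). It used the 75 analytes above the floor on at least 4 of 8 membranes, and an adjusted p (Benjamini-Hochberg) under 0.05 made a call. The interactions served as the error, with 4 residual degrees of freedom. A second limma fit held the interactions of line with RT and of line with IL-7, with 2 residual degrees of freedom. The interaction of RT with IL-7 was in neither fit and stayed in the error. A matched pair was 1 membrane of each level of the factor under test, alike in the other factors. No paired analysis by animal was possible because each group had 1 membrane and the labels gave no numbers linking animals.

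There were 19 lists of analytes fixed by function. They covered chemokines attracting T and NK cells, lymphoid homing and B cell factors, Th2, Treg and eosinophil chemokines, monocyte chemokines, neutrophil chemokines, and neutrophil granule and myeloid products. Further lists held lymphocyte cytokines, common gamma chain cytokines, antigen-presenting cell cytokines, inflammatory cytokines of the IL-1, TNF and IL-6 families, angiogenic growth factors, and matrix proteins. The remaining lists were endothelial and adhesion molecules, adipose products, plasma proteins of liver, platelet content, IGF binding proteins, stress secreted factors and shed receptors. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean signal, and that percentile carries no p-value. A list was described where at least 2 members were measured.

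Named analytes followed a fixed rule. It took the 8 largest differences per direction that passed the rule of size in each of 9 comparisons of single membranes. For line, RT and IL-7 it took every limma call and the 10 largest differences per direction alike in 4 of 4 pairs. For each interaction it took the 5 smallest p, and IL-7 and the members of a described list were added. The values of 1 analyte that the rule names are not reported here.

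The alternatives tried were median centring of the membranes on the analytes above the floor on all 8, floors of 0.5% and 2%, a threshold of 2-fold, and single spots in place of their mean. For limma they were also no filter on low values, an intensity trend, treatment as a block, and leaving out each membrane in turn. A floor per membrane was added after the values were seen.

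The methods were tried on simulated values of known change, with 10 changed analytes in each of 50 simulations. With 75 analytes, limma recovered 50.2% of changes of log2 1 for line, 53.4% for RT and 56.2% for IL-7. At log2 2 it recovered 97.0%, 98.6% and 99.0%. False calls made up 5.19% to 7.93% of calls for these 3 factors. Interactions of log2 2 were recovered in 19.2% of cases for line by RT and 23.6% for line by IL-7, and those of log2 4 in 95.8% and 96.2%. False calls made up 10.3% and 9.92% of the interaction calls at log2 2, and 4.77% and 7.50% at log2 4. With 111 analytes and a spot variation of 10%, the rule of size recovered 99.8% of 2-fold changes with 0 false calls. Here the 2 simulated membranes differed only by spot error and the 10 changed analytes. The changed analytes were drawn only from those above 2 times the floor on the TC-1 buffer membrane. A 2-fold fall therefore kept its true value above the floor, and recovery of changes nearer the floor was not tried. Neither these nor the limma simulations held a shift of a whole membrane, and those of limma held no floor. The shares of false calls therefore do not cover such shifts. Of 40 simulated lists of 6 analytes without a shift, 4 lay beyond the 2.5 or 97.5 percentile, against 19 of 40 lists shifted by 1 SD. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.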

Results

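Cytokines and other secreted proteins were measured in mouse tumour lysates to relate their profiles to radioresistance and to the response to radiation and interleukin-7. TC-1 is a mouse epithelial tumour line expressing HPV16 E6 and E7, and TC-1/IR is its radiation-resistant counterpart. Female C57BL mice aged 10 weeks received 100000 TC-1 or 300000 TC-1/IR cells under the skin of the right thigh. Treatment began at a tumour volume of about 100 mm3, 8 to 10 days after inoculation. Mice received buffer, whole-body gamma irradiation (RT, 2 Gy daily for 4 days), rhIL-7-hyFc (IL-7, 50 µg subcutaneously on days 0 and 7) or both. The drug is a long-acting recombinant human IL-7 fused to a hybrid Fc. Lysates of tumours taken at the endpoint were cleared by centrifugation at 10000 × g for 5 min before the array.

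The 2 lines and 4 treatments made 8 groups with 1 membrane each. The sample titles call the lysates pooled, whereas the description of the design speaks of independent tumours from individual mice, so the number of animals behind a membrane is unclear. No group had a replicate membrane, and the number of arrays limits the precision. Duplicate spots give technical error only. Above the floor of 2.49, the duplicate spots had a median coefficient of variation of 5.02% to 11.1% per membrane.

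The analytes summed to 1204 intensity units on the TC-1 buffer membrane, 1252 after RT, 1449 after IL-7 and 1173 after both. For TC-1/IR the sums were 765, 1473, 1495 and 739 in the same order. Analytes above the floor numbered 68, 86, 91 and 78 for TC-1 and 38, 64, 48 and 36 for TC-1/IR. In all, 28 analytes were above the floor on all 8 membranes and 15 on none. Osteopontin, CD14 and pentraxin 2 gave the strongest signals. Pentraxin 2 reached 249 on the TC-1/IR IL-7 membrane, and osteopontin reached 188 on the TC-1/IR RT membrane. The 5 strongest analytes held 36.3% to 44.4% of the signal on TC-1 membranes and 53.9% to 59.1% on TC-1/IR membranes.

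**Figure D1:**
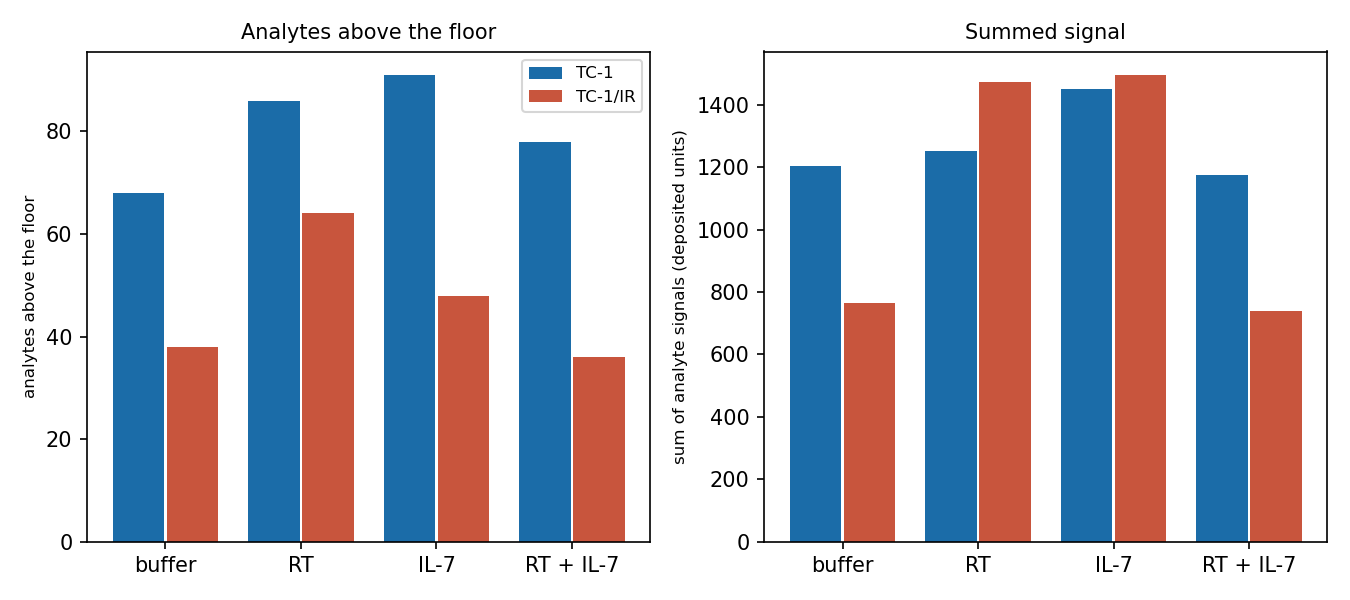
Bars give the number of analytes above the floor and the summed intensity for each of the 8 membranes, 1 membrane per group. The TC-1/IR sums run from 739 to 1495 and the TC-1 sums from 1173 to 1449.

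The first comparison asked how tumours of the resistant line differ from those of the sensitive line over the 4 treatments. IL-1ra (Il1rn, Entrez 16181), the receptor antagonist that blocks IL-1, fell by 2.46 on the log2 scale (SE 0.50, limma adjusted p = 0.0100, lower in 4 of 4 pairs). Its mean was 68.4 ± 24.2 in TC-1 and 14.4 ± 8.54 in TC-1/IR (SD, n = 4 membranes each). IL-11, a cytokine of the IL-6 family, averaged 10.7 ± 1.40 and 3.15 ± 0.318. It fell by 1.75 (SE 0.21, limma adjusted p = 0.0035, 4 of 4 pairs). CCL22, which attracts regulatory T cells, averaged 12.1 ± 1.13 and 2.37 ± 2.60, with 1 of 4 TC-1/IR membranes above the floor. The IL-7 reading (Il7, Entrez 16196) averaged 12.0 ± 2.40 in TC-1 and 2.75 ± 1.85 in TC-1/IR. It fell by 1.87 (SE 0.30, limma adjusted p = 0.0047, 4 of 4 pairs), with 2 of 4 TC-1/IR membranes below the floor and set to it, and 2 of the 4 membranes of each line were from mice given the drug.

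Pentraxin 2 (Apcs, Entrez 20219), a plasma protein made by liver, was the 1 analyte called higher. It averaged 106 ± 13.7 in TC-1 and 190 ± 39.7 in TC-1/IR, a difference of 0.83 (SE 0.22, limma adjusted p = 0.0205, higher in 4 of 4 pairs). It was called in 8 of 15 alternatives and in 3 of the 8 fits that left out a membrane, with adjusted p from 0.0045 to 0.0906. It was not called without TC-1 RT, TC-1 IL-7, the TC-1/IR IL-7 membrane or either combination, nor with an intensity trend or a floor per membrane. IFN-γ, IL-4, IL-27 p28, FGF-21, GDF-15 and G-CSF were at or below the floor on all 4 TC-1/IR membranes. Their falls are lower bounds, from at least 1.75-fold for G-CSF to at least 2.37-fold for IL-4. Endostatin, a fragment of collagen that restrains vessels, was 2.89-fold lower and IL-33, an alarmin of epithelium, 2.12-fold lower. Other analytes called lower were IL-28A/B, IGFBP-2, Gas 6, IL-1α, LIF, TNF-α, IL-13, IL-15, M-CSF, LDL R, CX3CL1, CXCL9, pentraxin 3, Pref-1, Reg3G, TIM-1 and VEGF. CX3CL1 was lower in 3 of 4 pairs and the rest of these in 4 of 4. IL-10 was higher by 0.67 and Serpin F1 by 0.92 in 4 of 4 pairs without passing the test (limma adjusted p = 0.0802 and 0.0909). With treatment as a block, limma called 3 analytes higher and 34 lower.

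In all, limma called 31 of 75 analytes for line, 1 higher and 30 lower, and 38 had an unadjusted p under 0.05. The median difference over the 75 was -0.58. In 4 of 4 pairs, 3 analytes were higher and 40 lower, against 9.38 in total by chance (12.5%). That share leaves out shifts of whole membranes, which move many analytes together. The median shift between the lines was -0.77 with buffer, 0.13 after RT, -0.41 after IL-7 and -0.76 after both. The count of pairs was not repeated after centring. After median centring of the membranes, 27 were called, 5 higher and 22 lower, and 23 of the 31 were among them. IL-10, osteopontin, complement factor D and Serpin F1 joined pentraxin 2 on the higher side. CXCL9, G-CSF, IL-1α, IL-13, IL-15, IL-33, M-CSF and Pref-1 were no longer called after centring. Their differences went from between -1.08 and -0.77 (SE 0.20 to 0.34) to between -0.63 and -0.31 (SE 0.20 to 0.27). The count was 7 without the TC-1 RT membrane, 9 without TC-1 IL-7, 13 without the TC-1/IR combination and 15 without the TC-1 combination, and 38 without TC-1/IR RT. CCL22, FGF-21, IL-4, IL-7, IL-11 and IL-28A/B were called whichever membrane was left out. Of these, only IL-11 was above the floor on every membrane. FGF-21 and IL-4 were set to the floor on every TC-1/IR membrane, and CCL22 and IL-28A/B on all of them but RT. IL-7 was set to it with buffer and after the combination. Values set to the floor have no spread, which favours a stable call. Over the alternatives the limma adjusted p of IL-4 reached 0.384.

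Of all 75 analytes tested, 30 were called lower for line, so a list with a share near that one is not set apart by its count. Among the lists, inflammatory cytokines of the IL-1, TNF and IL-6 families had 6 of 7 tested members called lower, among them IL-1ra, IL-11 and LIF. It was 7 when adjusted over the list alone. IL-1ra blocks IL-1, so the members of this list do not all act in the same direction. Common gamma chain cytokines had 3 of 4 lower (IL-4, IL-7 and IL-15), and 3 adjusted over the list alone. Lymphocyte cytokines had 3 of 5 lower, among them IFN-γ and IL-13, and 5 adjusted over the list alone, 4 lower and IL-10 higher. For antigen-presenting cell cytokines it was 2 of 4, and 4 adjusted over the list alone, 3 lower and IL-10 higher. T and NK cell chemokines had 2 of 5 lower (CXCL9 and CX3CL1), with 2 adjusted over the list alone, and stress factors 2 of 4 (GDF-15 and FGF-21), also with 2 adjusted over the list alone. Shed receptors had 2 of 5 lower (LDL R and TIM-1), with 2 adjusted over the list alone. Plasma proteins had 1 higher (pentraxin 2) and 1 lower of 6, with 2 adjusted over the list alone.

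The remaining lists had at most 1 member called for line. It was CCL22 of 3 Th2 and Treg chemokines (2 adjusted over the list alone), M-CSF of 3 monocyte factors (1) and G-CSF of 3 neutrophil chemokines and growth factors (1). It was IGFBP-2 of 4 IGF binding proteins, with 2 adjusted over the list alone. Pentraxin 3 of 4 neutrophil granule and myeloid products, VEGF of 5 angiogenic factors, endostatin of 6 matrix proteins and Pref-1 of 4 adipose products were called, with 0 adjusted over the list alone in each. Platelet content had 0 of 3 in limma, and 0 adjusted over the list alone. Endothelial and adhesion molecules, with 2 members measured, had 0 called by the rule of size between the buffer membranes. Of the lymphoid homing factors too few were measured there.

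After centring, 22 of all 72 analytes tested were called lower. Inflammatory cytokines then had 4 of 7 lower (IL-1ra, IL-11, LIF and TNF-α), with 5 adjusted over the list alone. Common gamma chain cytokines had 2 of 3 (IL-4 and IL-7), with 2 adjusted over the list alone. Of 4 lymphocyte cytokines IFN-γ and IL-4 were lower and IL-10 higher (3 adjusted over the list alone), and of 4 antigen-presenting cell cytokines IL-27 p28 was lower and IL-10 higher (2). CX3CL1 was the 1 T and NK cell chemokine of 5 still lower, with 1 adjusted over the list alone. M-CSF and G-CSF were no longer called, so no member of the monocyte list or of the neutrophil chemokine list was. Matrix proteins had osteopontin and Serpin F1 higher and endostatin lower, with 3 adjusted over the list alone, and among adipose products complement factor D was higher, with 0 adjusted over the list alone in limma.

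**Figure D2:**
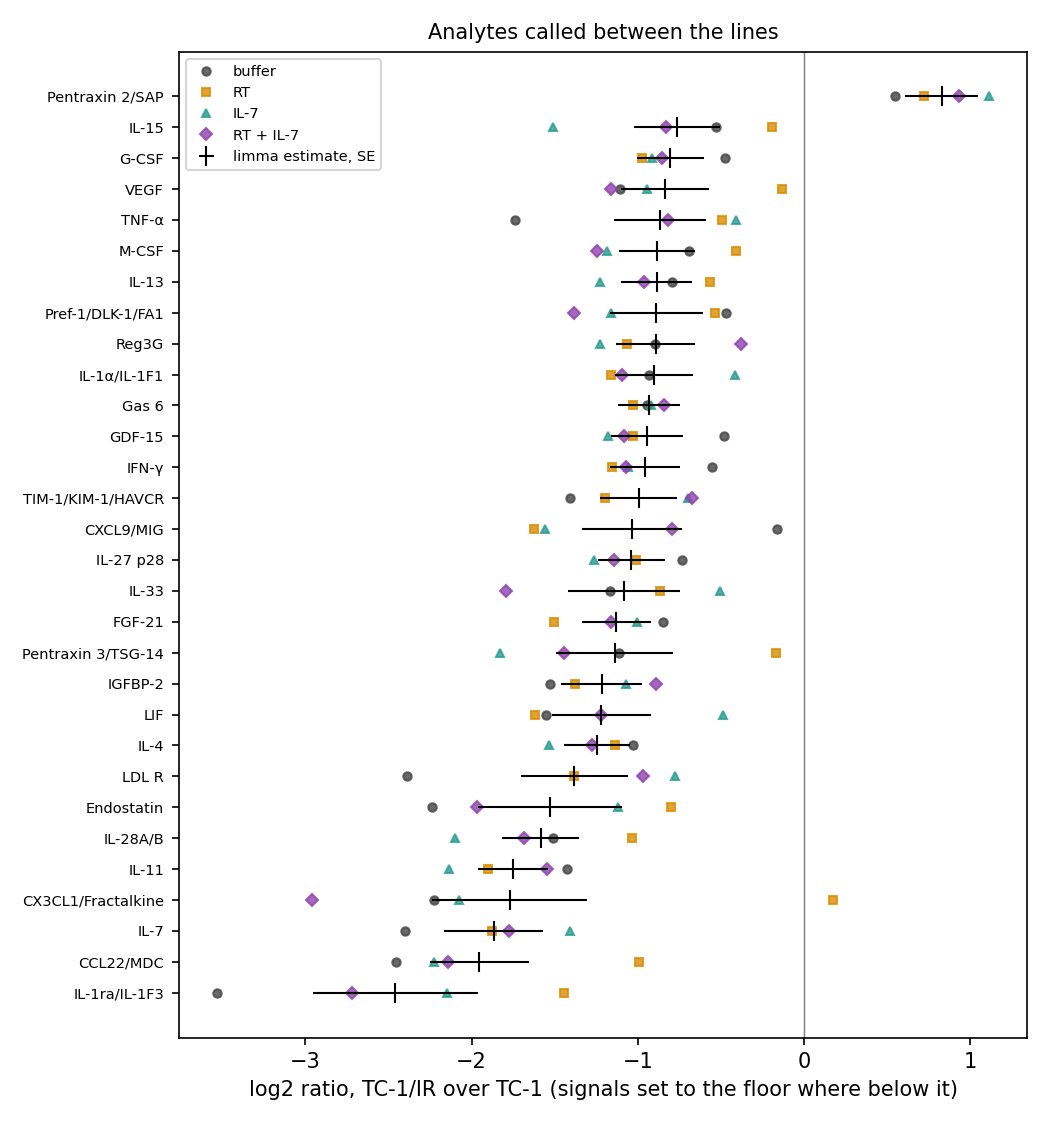
Log2 difference between TC-1/IR and TC-1 for 30 of the 31 analytes called by limma, with the limma estimate and its standard error as crosses and the 4 treatments as points. The estimate of pentraxin 2 lies above 0 and those of the other analytes below, down to -2.46 for IL-1ra.

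In the buffer groups alone, which compare untreated tumours, IL-1ra was 11.5-fold lower in TC-1/IR than in TC-1, at 4.13 against 47.7 (log2 -3.53, SE 0.27). CCL22 was at least 5.48-fold lower, IL-7 at least 5.28-fold and CX3CL1 at least 4.68-fold. LDL R, endostatin and TNF-α were also among the 8 largest differences on that side. DPPIV, a surface peptidase, was at least 2.63-fold higher in TC-1/IR, and DKK-1, a Wnt antagonist, and IL-10 were 1.88-fold and 1.81-fold higher. Inflammatory cytokines had 6 of 7 measured members lower, or 4 of 7 after centring. By the rule of size 3 analytes were higher and 37 lower, and 32 of the 72 above the floor were neither. Centring removed a median shift of -0.77 and left 13 higher and 22 lower, with all 3 and 22 of the 37 kept.

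Irradiation was examined over the 4 membranes with and the 4 without RT. CXCL10 (Cxcl10, Entrez 15945), an interferon-induced chemokine for T and NK cells, rose from 12.4 ± 2.03 to 30.9 ± 8.13 (SD, n = 4 membranes each). The difference was 1.29 (SE 0.21, 2.44-fold, limma adjusted p = 0.0280), and CXCL10 was higher in 4 of 4 pairs, by 1.13 to 1.46. After centring the pairs spread wider, from 0.35 for RT against buffer in TC-1/IR to 2.24 for the combination against IL-7 in TC-1/IR. CXCL10 was called in 0 of the 8 fits that left out a membrane, and its limma adjusted p ran from 0.0121 to 0.273 over the alternatives. Its difference stayed between 1.18 and 1.44 over the same settings. Myeloperoxidase (Mpo, Entrez 17523), an enzyme of neutrophil granules, was lower in 4 of 4 pairs, by a mean of -1.99 (SE 0.65), without passing the test (limma adjusted p = 0.636). Its pairs ran from -4.65 to -0.36, and the difference was -1.17 without the TC-1/IR IL-7 membrane. IL-12 was lower in 4 of 4 pairs by a mean of -0.47 (limma adjusted p = 0.969).

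For RT limma called 1 of 75 analytes, and 2 had an unadjusted p under 0.05. In 4 of 4 pairs, 1 analyte was higher and 2 lower, fewer than the 9.38 that independent pairs give by chance. In TC-1/IR the rule of size gave 31 higher and 2 lower for RT against buffer. For the combination against IL-7 alone it gave 4 higher and 31 lower. After centring these counts were 12 and 12, and 14 and 14. With RT by IL-7 left in the error, a low count does not show the absence of an RT effect. T and NK cell chemokines had 1 of 5 called, 1 adjusted over the list alone, with a median at percentile 99.95 of matched random lists. Neutrophil granule and myeloid products had 0 of 4 called by limma, at percentile 0.48. The pair with the TC-1/IR IL-7 membrane enters this median, with a log2 ratio of -2.21 for CD14 and a bound of -1.56 for chitinase 3-like 1. For RT against buffer in TC-1/IR the ratios were 1.68 for CD14, 1.06 for pentraxin 3 and -0.36 for myeloperoxidase. The percentile without the TC-1/IR IL-7 membrane was not computed. Over the 17 lists and 3 factors, 3 of 51 medians lay beyond the 2.5 or 97.5 percentile, with 2.55 given by chance.

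In TC-1, CXCL9 was 2.75-fold higher after RT than with buffer, at 7.68 against 2.79, and CXCL10 2.19-fold higher. CCL5, also a T cell chemokine, was at least 2.26-fold higher, at 5.62 with a wide spot SD of 2.59 (log2 SE 0.49). Serpin E1, an inhibitor of fibrinolysis, was 2.25-fold higher, and IL-33 1.97-fold higher, at 70.2 against 35.6. Amphiregulin, CCL17 and FGF acidic completed the 8 largest increases. Myeloperoxidase was 2.78-fold lower, at 9.11 against 25.3, and TNF-α and CX3CL1 were 1.55-fold and 1.53-fold lower. T and NK cell chemokines had 4 higher (CXCL9, CXCL10, CXCL16 and CCL5) and 1 lower (CX3CL1) of 7 measured, with a median at percentile 99.8. By the rule of size 17 analytes were higher, 3 lower and 66 neither. After centring 15 were higher and 1 lower, and 13 of the 17 and myeloperoxidase were kept.

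In TC-1/IR, IL-1ra was 4.76-fold higher after RT, at 19.7 against 4.13. Fetuin A, a plasma protein, was 3.24-fold higher at 135 against 41.5, and CD14, a coreceptor of monocytes for endotoxin, 3.19-fold higher at 166 against 51.8. CD40 was at least 3.86-fold, CX3CL1 at least 3.45-fold and CXCL2 at least 3.18-fold higher, and chemerin and complement factor D 3.29-fold and 3.03-fold. DKK-1 was 1.80-fold lower and CXCL16 at least 1.78-fold lower, the latter from 4.425 with buffer (spot SD 2.06, log2 SE 0.49). Of 6 measured T and NK cell chemokines, 4 were higher (CX3CL1, CCL3/CCL4, CCL5 and CXCL10) and 1 lower (CXCL16). The rule of size called 31 analytes higher, 2 lower and 34 neither. After centring, which removed a median shift of 0.84, 12 were higher and 12 lower, with 12 of the 31 kept, but not CXCL10.

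The effect of RT was tested for a difference between the lines. For line by RT limma called 0 of 75 analytes, and 0 had an unadjusted p under 0.05. RBP4, CXCL2, CD40, CCL19 and leptin had the smallest p, each with an adjusted p of 0.999 in limma. A difference between the lines in the response to RT was therefore not shown for any analyte above.

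**Figure D3:**
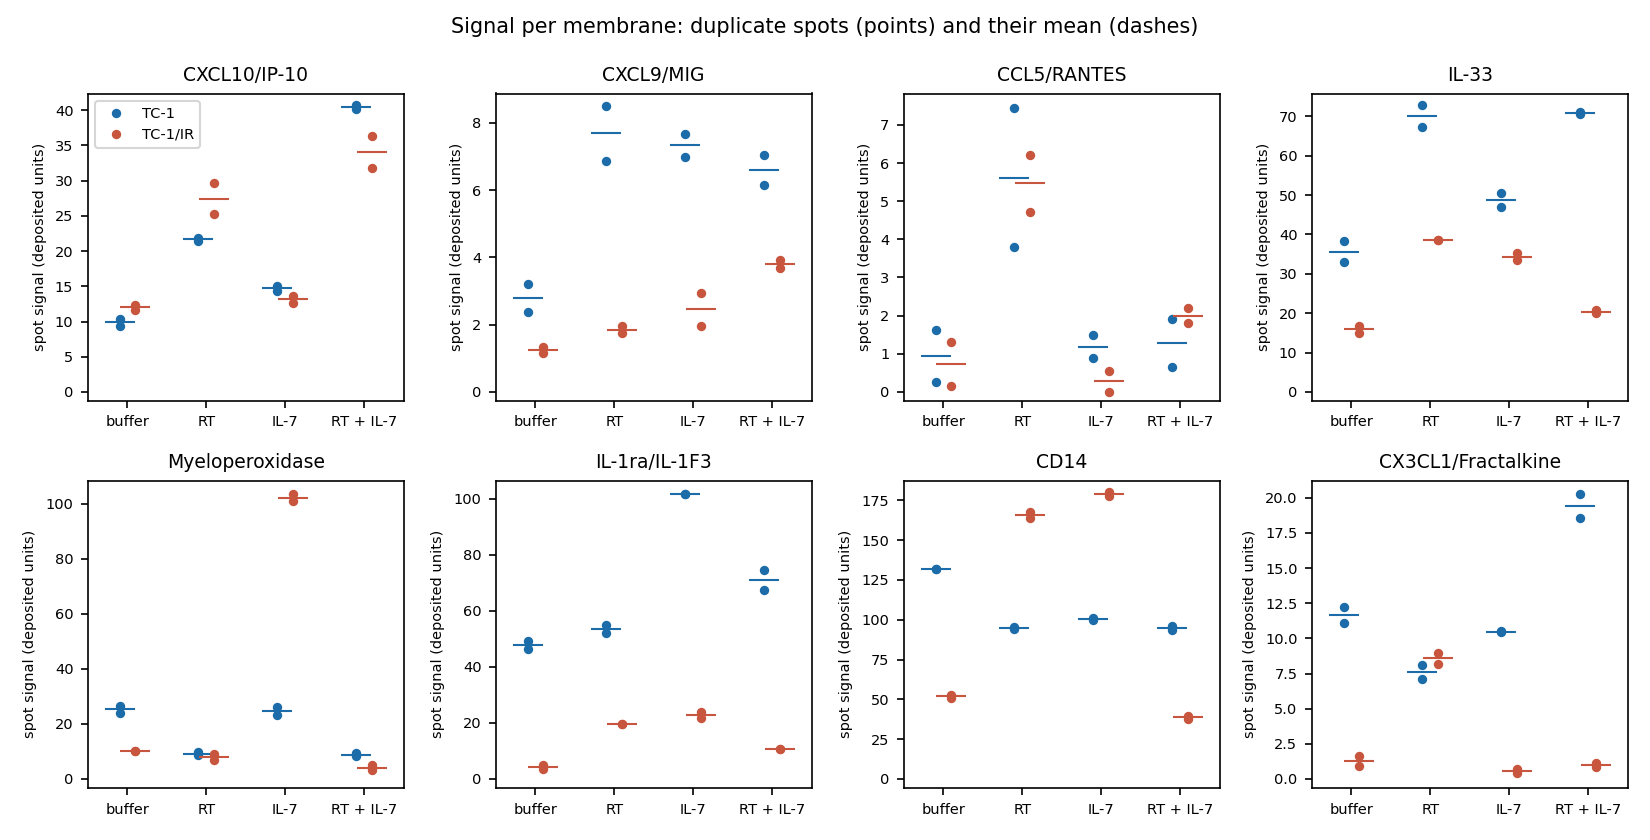
Spot intensity of 8 analytes on each of the 8 membranes, with duplicate spots as points and their mean as a dash. CXCL10 is highest after RT with IL-7 in both lines, at 40.5 and 34.0, and myeloperoxidase reaches 102 on the TC-1/IR IL-7 membrane alone.

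The comparison of membranes with and without rhIL-7-hyFc addressed the effect of the cytokine on the tumour. CXCL10 was the 1 analyte higher in 4 of 4 pairs, by a mean of 0.48, without passing the test (limma adjusted p = 0.974). Limma called 0 of 75 analytes for IL-7, and 0 had an unadjusted p under 0.05, against 8 after centring. No fit held a term for RT by IL-7. In TC-1/IR the rule of size gave 26 higher and 3 lower for IL-7 against buffer. For the combination against RT it gave 3 higher and 31 lower. After centring these counts were 19 and 11, and 22 and 12. Changes in opposite directions cancel in the mean and add to the error, so 0 calls does not show that IL-7 had no effect. The IL-7 reading of this mouse array was 13.2 with buffer and 12.5 with the drug in TC-1. In TC-1/IR it was 0.595 with buffer and 4.69 with the drug, but 3.80 after RT without the drug and 1.905 after RT with it. The values of 0.595 and 1.905 lay below the floor. Whether its antibody binds the human drug is not given in the sources used here.

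In TC-1, amphiregulin, a ligand of the EGF receptor, was at least 3.23-fold higher with IL-7 than with buffer. CCL19, which guides T cells and dendritic cells to lymphoid tissue, was at least 2.84-fold higher, and CCL17 was 2.83-fold higher. Angiopoietin-like 3, LIX and angiopoietin-2 were at least 3.03-fold, 2.62-fold and 2.42-fold higher, and Serpin E1 and CXCL9 2.75-fold and 2.63-fold. TNF-α was 1.58-fold lower. T and NK cell chemokines had 2 higher (CXCL9 and CXCL16) and 0 lower of 6, and lymphoid homing factors 1 higher (CCL19) of 3. By the rule of size 29 analytes were higher, 1 lower and 61 neither. Centring removed a median shift of 0.14 and left 17 higher and 1 lower, with 17 of the 29 and TNF-α kept.

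In TC-1/IR, myeloperoxidase was 9.99-fold higher with IL-7 than with buffer, at 102 against 10.2 (log2 3.32, SE 0.02). IL-1ra was 5.54-fold, CD14 3.45-fold and complement factor D 3.39-fold higher. Chitinase 3-like 1 and lipocalin-2, both products of neutrophils and macrophages, were at least 2.95-fold and 2.65-fold higher, and fetuin A and chemerin 3.01-fold and 2.84-fold. DPPIV was at least 2.63-fold lower, DKK-1 1.89-fold and CXCL16 at least 1.78-fold (log2 SE 0.49 for CXCL16). Neutrophil granule and myeloid products had 4 of 5 measured members higher, with a median at percentile 99.58, or 99.7 after centring. MMP-9, also of that list, was at or below the floor on both membranes. Of 2 measured T and NK cell chemokines 1 was lower, at percentile 0.74, or 5.36 after centring. The rule of size called 26 analytes higher, 3 lower and 24 neither. After centring, which removed a median shift of 0.49, 19 were higher and 11 lower, with 19 of the 26 and all 3 kept.

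For line by IL-7 limma called 0 of 75 analytes, and 1 had an unadjusted p under 0.05. That was DPPIV, with a difference between the lines in the response of -1.74 (SE 0.62, limma adjusted p = 0.982). Angiopoietin-like 3, CX3CL1, CXCL2 and Serpin E1 followed, each at an adjusted p of 0.982 in limma. Myeloperoxidase was not among the 5 smallest p of this test.

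The combination was compared with buffer in each line. In TC-1, CXCL10 was 4.08-fold higher after RT with IL-7, at 40.5 (log2 2.03, SE 0.07). CXCL9 was 2.36-fold, CCL17 2.13-fold, IL-33 1.99-fold and CX3CL1 1.67-fold higher, and CCL19, CCL12 and angiopoietin-like 3 at least 1.99-fold, 1.83-fold and 1.83-fold. Myeloperoxidase was 2.85-fold lower, PD-ECGF at least 2.45-fold, RBP4 1.95-fold and TNF-α 1.89-fold. TIM-1, endostatin and IGFBP-2 were lower by 1.56-fold to 1.67-fold. T and NK cell chemokines had 4 of 5 higher and 0 lower, with a median at percentile 99.5. By the rule of size 14 analytes were higher, 11 lower and 58 neither. Centring removed a median shift of -0.38 and left 31 higher and 3 lower, with all 14 and 3 of the 11 kept, namely myeloperoxidase, PD-ECGF and RBP4.

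In TC-1/IR, CXCL10 was 2.83-fold higher after the combination than with buffer, at 34.0 against 12.0. IL-1ra was 2.61-fold, CCL19 2.02-fold, leptin 1.86-fold, LDL R 1.85-fold, chemerin 1.68-fold and CXCL9 at least 1.53-fold higher. DPPIV was at least 2.63-fold lower, Serpin E1 2.57-fold and myeloperoxidase 2.51-fold. Pref-1, DKK-1, IGFBP-6 and IL-12 were also lower, by at least 1.58-fold. Among T and NK cell chemokines, 2 of 3 were higher (CXCL9 and CXCL10). The rule of size called 7 analytes higher, 8 lower and 29 neither. After centring, which removed a median shift of -0.37, 13 were higher and 6 lower, with all 7 and 5 of the 8 kept.

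The combination was also compared with RT alone, which asks what IL-7 adds to irradiation. In TC-1, CX3CL1 was 2.55-fold higher, at 19.4 against 7.60, CXCL10 1.87-fold, angiopoietin-like 3 1.63-fold and CCL19 1.58-fold. CCL5 was at least 2.26-fold lower (log2 SE 0.49) and IL-7 1.63-fold lower, at 8.53 against 13.9. IGFBP-2, PD-ECGF, leptin, Reg3G, LIF and endostatin were lower by 1.52-fold to 1.77-fold, with PD-ECGF at least 1.67-fold. Lymphoid homing factors had 1 of 2 higher (CCL19). By the rule of size 4 analytes were higher, 9 lower and 76 neither. Centring removed a median shift of -0.32 and left 10 higher and 1 lower, with all 4 and CCL5 kept.

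In TC-1/IR, CCL19 was 1.87-fold higher after the combination than after RT, CXCL16 at least 1.74-fold (log2 SE 0.41) and CXCL9 at least 1.53-fold. Serpin E1 was 6.40-fold lower, at 3.60 against 23.1, and CD14 4.28-fold lower, at 38.7 against 166. CD40, CX3CL1 and CXCL2 were at least 3.86-fold, 3.45-fold and 3.18-fold lower, and endostatin and IGFBP-6 3.42-fold and 3.07-fold. Matrix proteins had 5 of 7 lower and inflammatory cytokines 3 of 5, but after centring 1 matrix protein of 6 was lower (Serpin E1) and 1 higher, and 0 of 6 inflammatory cytokines were lower and 2 higher. The rule of size called 3 analytes higher, 31 lower and 32 neither. After centring, which removed a median shift of -1.21, 22 were higher and 12 lower. All 3 and 12 of the 31 were kept, but endostatin and IGFBP-6 were not.

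Over the 9 comparisons of single membranes, 4 of 157 list medians lay beyond the 2.5 or 97.5 percentile, and chance gives 7.85. The T and NK cell chemokines were on the high side in TC-1 after RT and in TC-1 after the combination. In TC-1/IR after IL-7 they were on the low side, with CXCL10 and CXCL16 alone measured, and came inside the limits after centring. The neutrophil granule and myeloid products were on the high side in TC-1/IR after IL-7. The comparisons with buffer share a membrane within each line, and lists share members, so these are not independent.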

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

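The floor set per membrane was chosen after the values were seen. The other alternatives were fixed beforehand. No named value changed its direction past the threshold under any alternative run. Apart from the counts below, 813 values were classed as the same, 201 as moved, 154 as weaker and 6 as stronger. The 201 classed as moved shifted without a change of direction past the threshold.

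With a floor of 2% (4.98), analytes called by the rule of size numbered 20 rather than 40 for the line in buffer. For RT they were 8 rather than 20 in TC-1 and 19 rather than 33 in TC-1/IR, and for IL-7 14 rather than 30 and 16 rather than 29. For the combination against buffer they were 10 rather than 25 and 6 rather than 15, and against RT 7 rather than 13 and 19 rather than 34. Limma called 10 analytes for line at this floor, where fewer analytes were tested. With 2-fold in place of 1.5-fold, the same 9 counts were 26, 7, 19, 13, 18, 5, 7, 2 and 21, by the construction of a stricter rule. With a floor of 0.5% (1.25), RT in TC-1/IR had 53, IL-7 in TC-1/IR 45 and the combination against buffer in TC-1/IR 27, and limma called 0 for RT. Under median centring IL-7 in TC-1 had 18. With a floor per membrane, the combination had 23 against buffer in TC-1/IR and 20 against RT in TC-1, and limma called 0 for RT. With an intensity trend in limma, RT had 0 called. Where no construction is named, the cause was not tested.

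The limma count for line was 27 after centring, 40 at the 0.5% floor, 25 without the filter, 36 with a trend, 32 with a floor per membrane and 37 with treatment as a block. When single membranes were left out it ran from 7 to 38. It was 7 without TC-1 RT, 9 without TC-1 IL-7, 15 without the TC-1 combination, 13 without the TC-1/IR combination and 38 without TC-1/IR RT. For RT, for IL-7 and for both interactions, the count ran from 0 to 0. CXCL10 for RT was called under 3 of 14 settings, with adjusted p from 0.0121 to 0.273, and 0.0473 after centring.

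Using 1 spot of each pair kept every count within 1.5 times. Values without scaling and without subtraction of negative controls were not run, being identical to those reported. Signal over background limits the TC-1/IR membranes most, where 36 to 64 of 111 analytes were above the floor.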

Other observations

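The comparisons of the combination with IL-7 alone and of the lines within each treatment, the splits of the membranes and the tests of background, brightness, spill-over and granule products were chosen after the results were seen. The brightness tests read counts from the median centring, a setting fixed beforehand. Against IL-7 alone, RT with IL-7 had CXCL10 2.75-fold higher and CX3CL1 1.85-fold higher in TC-1, and both held after centring. Myeloperoxidase was 2.77-fold lower and RBP4 2.29-fold lower. By the rule of size 2 analytes were higher and 20 lower, or 5 and 3 after centring. In TC-1/IR, CXCL10 was 2.59-fold and CCL19 at least 2.65-fold higher, with CXCL16 and CXCL9 also higher. Myeloperoxidase was 25.1-fold lower, at 4.08 against 102, CD14 4.63-fold and complement factor D 3.17-fold. There 4 analytes were higher and 31 lower, or 14 and 14 after centring.

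Compared with TC-1 under the same treatment, IL-1ra was 2.72-fold lower in TC-1/IR after RT, 4.43-fold after IL-7 and 6.58-fold after both, and IL-7 and CCL22 were lower in these 3 comparisons too. In numbers, 12 analytes were higher and 33 lower in TC-1/IR after RT, 6 and 53 after IL-7, and 2 and 44 after both. After centring the counts were 10 and 31, 12 and 31, and 7 and 29.

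Line, RT and IL-7 were each tested over 33 splits of the 8 membranes into 4 and 4, with the other factors in the fit. For line 1 split, the real one, gave as many as 31 calls, and the highest other gave 6. That is the smallest share the splits allow, and the other splits mix the lines, so their error holds the line difference. For RT 1 split of 33, the real one, gave 1 call, and the highest other gave 0. That call is CXCL10, which was called in 0 of 8 fits without a membrane, though its difference stayed between 1.18 and 1.44 over the settings. A count of 1 does not settle whether chance gave it. For IL-7 the real count was 0, which all 33 splits reach by construction, and the highest other gave 1, so nothing follows on chance.

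The lower signals of TC-1/IR tumours, from IL-1ra and CCL22 to IL-7, may be biological or come from the membranes. A constant amount of background taken off stays open for most of the 30, since a dim analyte cannot fall by more than its own signal. In 3 of the 30, IL-1ra, endostatin and IL-33, the fall in each pair exceeded 7.11 units. That was the largest fall in any pair of M-CSF, which stayed above the floor throughout, so such an amount alone does not give these 3 falls. This bound is a wide one, since it came from called analytes only. With buffer, the uncalled FGF acidic went from 3.835 to 3.555, PDGF-BB from 5.845 to 3.96 and IL-10 from 5.51 to 9.955. MMP-2, also uncalled, fell from 18.1 to 8.84. FGF acidic, PDGF-BB and IL-10 leave room for a smaller amount only, unless they differ between the lines themselves, which was not tested. A common brightness factor was argued against as the whole cause, since 22 of the 30 were still called lower after centring. The difference between the lines, and the larger number of TC-1/IR cells inoculated, remain open and untested, since both follow the line.

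After RT or IL-7 alone, most called analytes were higher in TC-1/IR, with sums of 1473 and 1495 against 765 for buffer. For RT a common brightness factor stays open, since 12 of 31 analytes were still higher after centring, among them IL-1ra, CD40 and CD14, and the others were not. For IL-7, 19 of 26 were still higher, among them myeloperoxidase, IL-1ra and CD14, which argues against such a factor as the whole cause. An effect of treatment stays open and untested in both cases, since each rests on 1 membrane per group.

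Myeloperoxidase on the TC-1/IR IL-7 membrane, at 102, may reflect granule protein in that lysate. Light from bright osteopontin spots was argued against, since myeloperoxidase was 7.96 on the TC-1/IR RT membrane, where osteopontin was 188 against 174 here. A common brightness factor was argued against, since the difference was 2.83 on the log2 scale after centring. More neutrophil granule protein stays open. Of the 4 other measured members of the list, 3 were higher, chitinase 3-like 1, lipocalin-2 and CD14, while pentraxin 3 was not. MMP-9, also of that list, was at or below the floor on this membrane and with buffer. CD14 was also 3.19-fold higher after RT in TC-1/IR, where myeloperoxidase was not higher. With 1 membrane per group, an unusual tumour and an effect of IL-7 on such protein cannot be told apart.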
